A study of Mus musculus with 12 samples.

How the data were processed

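RNA-seq libraries came from the left and right ventricles of control and Wnt LOF mouse hearts, 12 libraries in 4 groups of 3. The authors deposited a table of raw counts per Ensembl gene, and featureCounts of the Subread package and edgeR are named per the submitters' processing notes. The aligner, the tool versions, the genome build and the strand setting are not given in the sources used here, so overlapping and antisense genes cannot be told apart and no coordinates are printed. The count table had 41192 rows for 40594 genes, and the 598 further rows of a repeated gene, which hold equal counts, were left out. The authors also deposited 2 comparison tables with log2 fold changes, p-values, adjusted p-values, signed linear fold (ratio) values and log2 CPM per library, per the file headers. Groups were taken from the sample titles. The counts of near-identical copies and pseudogenes are uncertain, since the handling of shared reads is not given.

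Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. After filterByExpr by group, 15494 genes were tested. TMM factors ran from 0.961 to 1.04. A quasi-likelihood model with robust dispersion held 1 mean per group over all 12 libraries, and 5 contrasts were tested: Wnt LOF against control in each ventricle, right against left in each genotype, and the interaction. p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change was its size over the square root of F. The 33 gene lists and the design were fixed before the data were examined. They were tested with camera at a correlation of 0.01, with camera at an estimated correlation and with fry, for lists of at least 5 tested genes. Adjustment over the list alone was also computed.

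The rule for named genes takes Ctnnb1, Axin2 and Lef1, up to 8 called genes per direction with mean log2 CPM of at least 1 and groups that do not overlap, up to 4 called members per list, and a fixed set of channel, transcription factor and stress genes, of which 1 is not reported here. No gene was called in the planned model, so the rule was also applied to the control libraries with the replicate block. Members of lists named without a call, and Hey2, were chosen after their values were seen.

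Each computation was tested on simulated data with counts drawn from the means, library sizes and dispersions of the real libraries, 200 genes changed by a known fold, and 1 list shifted 1.25-fold. The shifted list was recovered in all 5 comparisons, and 0 or 1 of the 32 other lists passed. Counts were drawn independently for each gene, without the correlation between genes of real libraries. So the number passed does not show how often camera at the preset correlation passes unchanged lists in real libraries. For the 5 planned comparisons the simulated libraries also lacked differences by sex or heart.

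Whether equal replicate numbers pair libraries was checked by the correlation, over all 15494 tested genes, of deviations from the group means. Left and right libraries of control hearts had correlations of 0.411, 0.29 and 0.517 for numbers 1 to 3, and those of Wnt LOF hearts 0.191, 0.197 and 0.594. All exceed 0.1, so the numbers were taken to pair the ventricles. For number 1 of the Wnt LOF hearts the highest correlation with another number (0.201) exceeded its own (0.191), and in control hearts no correlation with another number exceeded 0.0727. For control hearts this held in 18 of 18 settings of the expression minimum and prior count, with values from 0.287 to 0.675, and for Wnt LOF hearts in 9 of 18, so that pairing depends on the setting. The genotype comparisons were not paired in all settings (0 of 18 in the LV and 5 of 18 in the RV). The pairing comes from the data, since the labels do not say that a number marks a heart. A correlation above 0.1 does not show a shared heart. Libraries numbered 3 exceeded it between genotypes too (0.233 in the LV and 0.306 in the RV). In every group the library numbered 3 was also the only one with Ddx3y, a Y-linked gene, above 1 CPM. So sex and a shared heart cannot be told apart in the correlations of number 3 (0.517 and 0.594).

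Alternatives were other size factors, total counts, other filters, DESeq2, fits of the compared groups alone, replicate blocks, and leaving out each library. A term for libraries with Y-linked reads, the block with the compared groups alone, and leaving out the libraries labelled WntLOF LV 1, WntLOF RV 1 and control LV 2 were added after the data were seen, as were fits of the control libraries alone without control LV 2 and, with the block, without the control pair numbered 2.

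A ventricle score was the median, over the 326 genes called in the control libraries with the block, of a library's log2 CPM placed between the control LV mean (-1) and the control RV mean (1). These genes rest on the block, which pairs control RV 2 with the library labelled control LV 2, so the score was also computed from the 67 genes called without that pair. On-off genes were autosomal genes with a mean log2 CPM above 0 and a gap of at least 2 on the log2 CPM scale between libraries and at least 2 libraries on each side. Genes with an unadjusted p under 0.05 between control ventricles in the fit with the block were left out of them, and 23 remained. Library pairs were also compared by chi-square per gene over genes with more than 50 counts in the pair. Chromosomes and the longest transcript length per gene came from GENCODE M21, matched by Ensembl identifier.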

Results

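RNA was sequenced from the left ventricle (LV) and the right ventricle (RV) of adult mouse hearts that were either control or carried a loss of function in the Wnt pathway (Wnt LOF). Wnt signalling is a cell communication pathway whose canonical branch acts through beta-catenin. The 12 libraries form 4 groups of 3, and the total count per library, in units of 1e+06 reads, ran from 13.3 to 19.2. Reads of mitochondrially encoded genes made up 4.62% to 8.29% of a library. The series title places the question in the difference between the ventricles in Wnt-dependent gene programmes and arrhythmia. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values measure the spread between libraries.

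Ctnnb1 (ENSMUSG00000006932), which encodes beta-catenin, was the first gene read because the labels do not name the gene that was targeted. In the RV its mean level was 531 ± 25.7 CPM (SD, n = 3) in control and 410 ± 52.4 CPM (SD, n = 3) in Wnt LOF, and the ranges did not overlap, which chance gives in 10% of splits of 3 against 3. The RV log2 fold change was -0.37 (SE 0.14), and its adjusted p was 1 by edgeR's quasi-likelihood test (unadjusted p 0.0203). In the LV the means were 511 ± 86.2 CPM (SD, n = 3) in control and 446 ± 75.4 CPM (SD, n = 3) in Wnt LOF, with overlapping ranges. The LV log2 fold change was -0.20 (SE 0.14) with an adjusted p of 0.999 by the edgeR test. The library labelled control LV 2 had 426 CPM, inside the range of the Wnt LOF libraries, and the library labelled WntLOF LV 2 had 532 CPM, inside the range of the controls. Ctnnb1 therefore does not separate the LV libraries by their labels. The origin of control LV 2 is in doubt, since it shared all on-off gene states with both libraries labelled WntLOF 1. Without it the LV ranges still overlapped, as WntLOF LV 2 lay between control LV 3 (509 CPM) and control LV 1 (598 CPM). Axin2, a transcriptional target of beta-catenin, had log2 fold changes of 0.07 (SE 0.31) in the LV and -0.23 (SE 0.31) in the RV, both smaller than their standard errors. Lef1, another target, was too low to test. The 15 tested genes of the Wnt target list had medians of 0.07 in the LV (camera adjusted p = 0.782) and -0.14 in the RV (camera adjusted p = 0.877), and none was called.

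**Figure D1:**
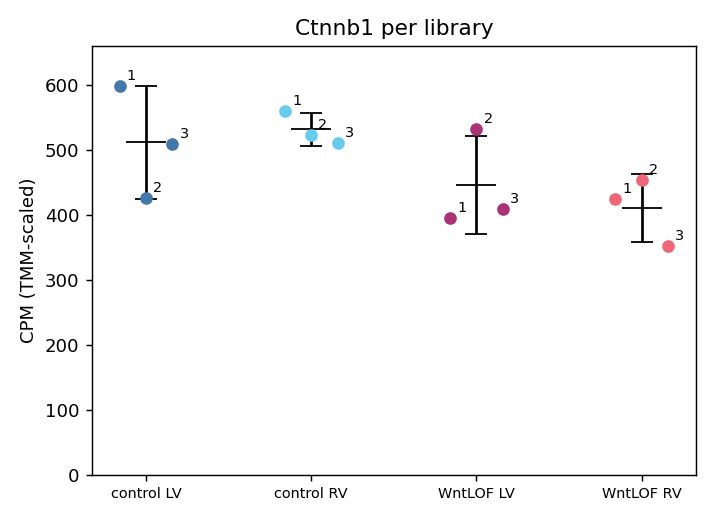
Ctnnb1 in TMM-scaled CPM (vertical axis) for each library (point, with its replicate number) of the 4 groups (horizontal axis). Bars give the mean and SD of 3 libraries, and control LV 2 sits at 426 CPM and WntLOF LV 2 at 532 CPM. The origin of control LV 2 is in doubt, since it shared all on-off gene states with both libraries labelled WntLOF 1.

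In the LV, Wnt LOF against control, genes of the heat shock and unfolded protein response lay lower, with 16 of 20 members below 0 and a median log2 fold change of -0.19. This list and 4 others of the 33 passed camera with a preset correlation of 0.01, none of the 5 with an estimated correlation (smallest adjusted p = 0.652 with an estimated correlation), and none by fry. Hspb1, a small heat shock protein, had a log2 fold change of -0.48 (SE 0.17), and Hspa1a, an inducible chaperone, had -1.06 (SE 0.44). Endothelial markers (median -0.12), immediate early genes (median -0.16) and hypoxia response genes (median -0.15) also lay lower, and potassium and pacemaker channels lay higher (median 0.11, 25 of 33 members above 0). No single gene reached an adjusted p of 0.05 over the 15494 genes tested by edgeR, or over any list alone. At an unadjusted p under 0.05 there were 442 genes, where uniform p-values over the genes tested give 775. Other splits of the same libraries gave 313 to 1508 genes, so 775 does not measure what chance gives in these libraries. DESeq2 called 0 genes, with 367 at an unadjusted p under 0.05. In simulated libraries of the same depth and dispersion, the test found 70.4% of genes changed 2-fold and 26.3% of genes changed 1.5-fold in this comparison. Those libraries were drawn without sex or heart differences, so these shares may not hold for the real ones. Without the libraries labelled WntLOF LV 1 and WntLOF RV 1, the endothelial list (median -0.052, adjusted p = 0.49) and the immediate early list (median -0.093, adjusted p = 0.0661) no longer passed. Without control LV 2 as well, all 5 lists passed camera with the preset correlation. The camera values were then -0.11 for endothelial markers (adjusted p = 0.037) and -0.17 for immediate early genes (adjusted p = 0.0042), as medians. Without control LV 1 no list passed, and the medians were -0.085 for heat shock, -0.052 for immediate early and -0.035 for hypoxia genes. Channels then had 0.085 and endothelial markers -0.086. Without control LV 2 there were 8 lists, and the channel median was 0.19. The calls also ended for the endothelial list without control LV 3 (median -0.059), for channels without the library labelled WntLOF LV 2 (0.083), and for immediate early (-0.096) and hypoxia genes (-0.087) without the library labelled WntLOF LV 3.

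In the RV, Wnt LOF against control, genes of fatty acid oxidation lay lower, with 24 of 27 members below 0 and a median log2 fold change of -0.17. This list and 4 others of the 33 passed camera with the preset correlation, none with an estimated one (smallest adjusted p = 0.837 with an estimated correlation), and none by fry. Pdk4, a kinase that holds back pyruvate oxidation, had a log2 fold change of -1.22 (SE 0.32), and Cpt1b, which moves fatty acids into mitochondria, had -0.27 (SE 0.09). Heat shock and unfolded protein response genes lay lower (median -0.19, 18 of 20 members). Interferon response genes lay higher (median 0.22, 20 of 22 members), as did macrophage markers (median 0.10), for example Cd68 with 0.51 (SE 0.18), and extracellular matrix genes (median 0.08). No single gene was called by edgeR or, adjusted over the list alone, within a list. At an unadjusted p under 0.05 there were 418 genes, where uniform p-values give 775. DESeq2 called 0 genes, with 346 at an unadjusted p under 0.05. Simulated libraries, drawn without sex or heart differences, gave 64.8% of genes changed 2-fold and 24.9% of genes changed 1.5-fold. Without the libraries labelled WntLOF LV 1 and WntLOF RV 1, the interferon list (median 0.088, adjusted p = 0.143) and the matrix list (median -0.0040, adjusted p = 0.654) no longer passed, the macrophage median rose to 0.20, and without the library labelled WntLOF RV 2 or the library labelled WntLOF RV 3 there were 8 lists. Single libraries also ended calls: macrophage markers without control RV 1 (median 0.076), control RV 3 (0.052) or the library labelled WntLOF RV 3 (0.020), interferon (0.17) and matrix genes (0.020) without control RV 3, and heat shock genes without control RV 2 (-0.091). The library labelled WntLOF RV 3 stood apart by the atrial muscle markers Myl7 (10.2 CPM, at most 1.26 in the other libraries), Myl4 (10.7, at most 2.86) and Sln (1.85, at most 0.167). The atrial list had a median of 0.10 and a mean of 0.50 in this comparison and was not called (camera adjusted p = 0.566). Without that library the fatty acid oxidation median was -0.22 and that of heat shock genes -0.14, and both passed. Without control RV 3 the fatty acid oxidation median was -0.092, and the list passed.

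Of the genes fixed in advance, Gja1, Kcnip2, Kcnj2, Irx5 and Nppb were not called in either genotype comparison by edgeR. Gja1, the gap junction protein connexin 43, had log2 fold changes of 0.09 (SE 0.12) in the LV and -0.07 (SE 0.12) in the RV. Kcnip2, a subunit of the transient outward current, had 0.12 (SE 0.13) and 0.21 (SE 0.13), and Kcnj2, an inward rectifier, had 0.16 (SE 0.14) and -0.09 (SE 0.14). Irx5, a transcription factor that patterns potassium channel expression, had -0.11 (SE 0.28) and 0.46 (SE 0.29). Nppb, a natriuretic peptide of stressed heart muscle, had -0.97 (SE 0.78) and 1.11 (SE 0.82). The libraries labelled WntLOF LV 1 and WntLOF RV 1, whose ventricle genes lay opposite to their labels, had 8.48 and 52.1 CPM of Nppb, and without them its log2 fold changes were -0.52 and 0.52. Without control LV 1, the LV value of Nppb was -0.38. The LV value of Irx5 was 0.17 without the library labelled WntLOF LV 1 and 0.14 without control LV 3, so its sign rests on single libraries, and that of Kcnj2 was -0.01 without the library labelled WntLOF LV 1.

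Across genes, the Wnt LOF effects in the LV and the RV had a Pearson correlation of 0.209 and a Spearman correlation of 0.104, over 15494 genes that are not independent replicates. Of these genes 53.6% had the same sign. At an unadjusted p under 0.05, 33 genes were in both lists, and 26 of the 33 had the same sign. Independent comparisons would share 11.9 genes, a number that does not apply if both ventricles came from the same hearts, since the 2 comparisons share no library but may share hearts. Over the 10 splits of the replicate numbers, the correlation of log2 CPM differences was 0.187 in the real split and up to 0.568 in the others.

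In control hearts, the RV had higher levels than the LV of the Wnt inhibitor Wif1 (ENSMUSG00000020218), of the water channel Aqp4 (ENSMUSG00000024411) and of the potassium channel Kcnd2 (ENSMUSG00000060882), as called by edgeR with the 6 control libraries alone. Wif1 was 2.83 ± 0.302 CPM (SD, n = 3) in the LV and 14.2 ± 3.63 CPM (SD, n = 3) in the RV. Aqp4 was 7.75 ± 0.831 CPM (SD, n = 3) and 27.6 ± 5.57 CPM (SD, n = 3). With the model fixed before the data were examined, no gene passed the threshold by edgeR (Wif1 log2 fold change 2.33, SE 0.88). At an unadjusted p under 0.05 there were 757 genes, where uniform p-values give 775. DESeq2 called 0 genes, with 729 at an unadjusted p under 0.05. With the 6 control libraries alone, edgeR called 9 genes: Wif1, Aqp4, Kcnd2, Cadps2, Sort1 and Dsg2 were higher and Papln, Bdh1 and Rtn4r lower in the RV.

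With the 6 control libraries alone and the replicate number as a block, a combination chosen after the data were seen, edgeR called 326 genes, 143 higher and 183 lower in the RV. This count is the highest of 21 fits recorded for this comparison, of which 15 called 0 genes. The block pairs control RV 2 with the library labelled control LV 2, which shared more on-off gene states with the library labelled WntLOF RV 1 than with control RV 2. Without the control pair numbered 2 the same fit called 67 genes from 4 libraries, 58 of them among the 326. In the fit without the block, leaving out control LV 2 left 1 gene called by edgeR, Kcnd2 (1.39, SE 0.12), while Wif1 (2.30, SE 0.25) and Aqp4 (1.90, SE 0.19) each had an adjusted p of 0.0552. With the block and without the control pair numbered 2, Wif1 (2.36, SE 0.16) and Aqp4 (1.97, SE 0.13) were called. In simulated libraries with 200 changed genes, of which 193, 197 and 190 were tested, the fit of the 6 control libraries with the block made 17, 15 and 40 false calls at 1.5-fold, 2-fold and 4-fold beside 121, 167 and 190 true ones, so its calls held more false ones than the threshold states. By the rule for named genes, applied to the 326, the largest rises were Wif1 (2.30, SE 0.14), Rp1 (2.25, SE 0.23), Ubxn10 (1.97, SE 0.16), Aqp4 (1.82, SE 0.12), Fam122b (1.28, SE 0.20), Kcnd2 (1.27, SE 0.08), Cenpf (1.23, SE 0.17) and Cfap61 (1.19, SE 0.20) on the log2 scale. The largest falls were Plekhh1 (-1.71, SE 0.18), Nrn1 (-1.60, SE 0.17), Slc24a2 (-1.31, SE 0.24), Cpxm2 (-1.19, SE 0.22), Igfals (-1.18, SE 0.20), Cdh4 (-1.15, SE 0.25), Gnb3 (-1.13, SE 0.12) and Rtn4r (-1.12, SE 0.15). In the fit with the 326 calls 6 of 27 fatty acid oxidation genes were called, all higher, among them Pdk4 (0.84, SE 0.09), Ucp3 (0.70, SE 0.08) and Cpt1a (0.29, SE 0.07), and 10 were called adjusted over the list alone. Of 32 potassium and pacemaker channels, Kcnd2, Kcna1 and Kcnj5 were called higher and Kcna5 and Kcne1 lower. Of 19 immediate early genes, 5 were called, all lower, among them Klf2 (-0.47, SE 0.10) and Jun (-0.35, SE 0.07).

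**Figure D2:**
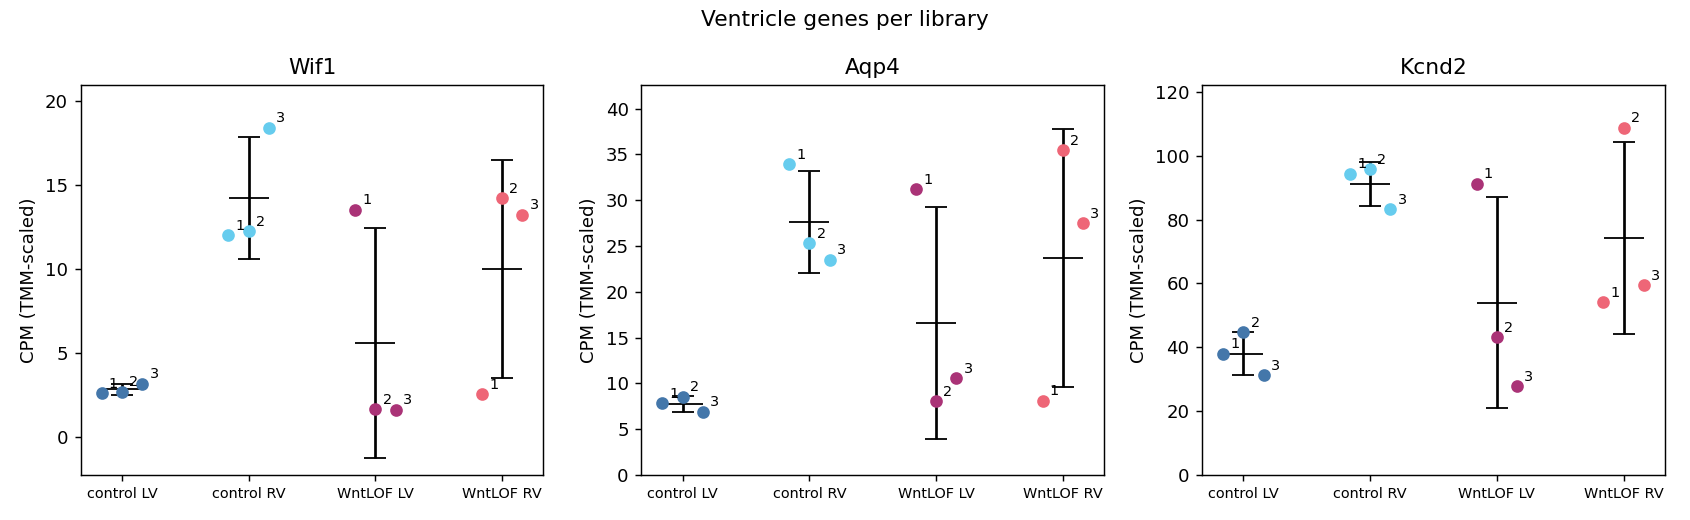
Wif1, Aqp4 and Kcnd2 in TMM-scaled CPM (vertical axes) for each library (point, with its replicate number) of the 4 groups (horizontal axes), with bars for mean and SD. The library labelled WntLOF LV 1 had 13.5 CPM of Wif1 and the library labelled WntLOF RV 1 had 2.56 CPM.

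In control hearts, 11 lists fixed in advance passed camera with the preset correlation between the ventricles, none with an estimated one (smallest adjusted p = 0.27 with an estimated correlation) and none by fry. Genes of the nuclear respiratory chain (median log2 fold change 0.23, 30 of 30 members above 0) and of fatty acid oxidation (median 0.20, 26 of 27 members) lay higher in the RV. Interferon response genes (median -0.28, 22 of 22 members below 0), immediate early genes (median -0.27), cell cycle genes (median -0.31) and extracellular matrix genes (median -0.17) lay lower. The control RV libraries also enter the comparison of Wnt LOF with control in the RV, with opposite sign. So the opposite medians there of fatty acid oxidation (-0.17) and interferon response genes (0.22) are not separate results. Erythroid genes (median 0.57) and neuronal and Schwann cell markers (median 0.41) lay higher, and endothelial (median -0.15), adipocyte (median -0.17) and cardiac transcription factor genes (median -0.08) lower. With each control library left out in turn, the respiratory chain, fatty acid oxidation and immediate early lists passed every time, and the other 8 did not without at least 1 library. The adipocyte list had 4 of 7 members below 0, and its median ran from -0.085 without control RV 1 to -0.66 without control RV 3. The cardiac transcription factor median ran from 0.016 without control LV 3 to -0.17 without control LV 2.

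In Wnt LOF hearts, RV against LV, the libraries of pair 1 stood apart from their labels. The library labelled WntLOF LV 1 had 13.5 CPM of Wif1 and 91.2 CPM of Kcnd2, inside the range of the control RV libraries. The library labelled WntLOF RV 1 had 2.56 CPM of Wif1, below every control library. With all 6 Wnt LOF libraries no gene was called by edgeR, and 746 genes had an unadjusted p under 0.05 where uniform p-values give 775. DESeq2 called 0, with 679 at an unadjusted p under 0.05. Without the libraries labelled WntLOF LV 1 and WntLOF RV 1, edgeR called 2 genes, Wif1 (log2 fold change 3.06, SE 0.25) and Aqp4 (1.76, SE 0.21). The pair was left out because of its values of such genes, so these 2 calls are conditioned on the outcome and are not independent evidence. In the same fit the control comparison called Wif1 (2.34, SE 0.19) and Aqp4 (1.83, SE 0.17). Nuclear respiratory chain genes (median 0.26, 26 of 30 members above 0), mitochondrially encoded genes (median 0.51) and macrophage markers (median 0.16) passed camera with the preset correlation, and none of the 3 with an estimated one (smallest adjusted p = 0.961 with an estimated correlation). With the replicate number as a block within genotype, edgeR called 1 gene, Mir6236 (log2 fold change -1.26, SE 0.11), which was chosen after its value was seen. Mir6236 was higher in the library labelled LV in all 3 pairs (37.1 and 15.2, 18.6 and 7.82, and 15.7 and 6.71 CPM in LV and RV of pairs 1 to 3), so its call rests on the labels of pair 1 as given. Without the library labelled WntLOF RV 1 alone edgeR called 1 gene, and 6 lists passed without it or without the library labelled WntLOF LV 1. The mitochondrially encoded call ended without the library labelled WntLOF LV 1 (median 0.41), WntLOF LV 3 (0.42) or WntLOF RV 2 (0.27). The macrophage call ended without the library labelled WntLOF LV 1 (0.12), WntLOF LV 2 (0.11) or WntLOF RV 3 (0.087). Respiratory chain genes passed each time, with medians from 0.14 to 0.41. Cox7a1 and Cox5b, subunits of cytochrome oxidase, had log2 fold changes of 0.78 (SE 0.26) and 0.82 (SE 0.30).

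**Figure D3:**
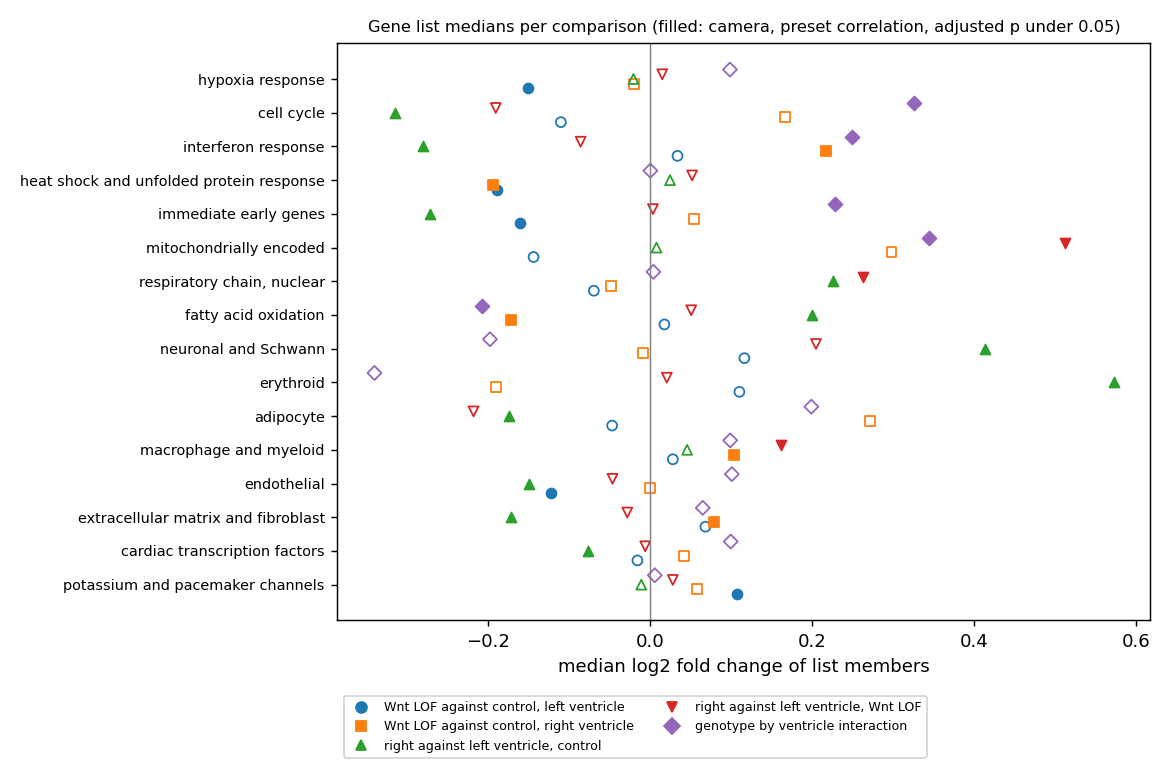
Median log2 fold change of list members (horizontal axis) for the lists that passed camera with the preset correlation in at least 1 comparison (vertical axis), with a marker per comparison, filled where that list passed. Fatty acid oxidation lay at 0.20 in control hearts, RV against LV, and at -0.17 for Wnt LOF against control in the RV. Both comparisons use the control RV libraries, with opposite sign, so these are not separate results. The list lay at 0.018 for Wnt LOF against control in the LV and at 0.051 in Wnt LOF hearts, RV against LV.

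The interaction asks whether the Wnt LOF effect differed between ventricles. It uses the same libraries as the other comparisons, so its values are not independent of theirs. No gene was called by edgeR or by DESeq2, with 312 and 256 genes at an unadjusted p under 0.05. For the edgeR count, uniform p-values give 775. By camera with the preset correlation 5 lists passed, and none with an estimated one (smallest adjusted p = 0.808 with an estimated correlation). Fatty acid oxidation genes had a median interaction of -0.21, with Ucp3 at -0.90 (SE 0.37). Mitochondrially encoded genes (median 0.34), immediate early genes (0.23), interferon response genes (0.25) and cell cycle genes (0.33) had positive medians. Without the libraries labelled WntLOF LV 1 and WntLOF RV 1 only the mitochondrially encoded list passed (adjusted p = 0.00139), and fatty acid oxidation did not (adjusted p = 0.524). The mitochondrially encoded list had 7 tested genes, and single libraries ended its call. These were control LV 3, RV 1 or RV 2, or those labelled WntLOF LV 1, LV 3, RV 2 or RV 3 (medians 0.18 to 0.37). It passed without each of the others (medians 0.52 to 0.61). Leaving out control LV 1 gave 3 lists, the library labelled WntLOF LV 3 gave 2 and the library labelled WntLOF LV 2 gave 9. With the replicate block within genotype edgeR called 1 gene, Mir6236 (-1.55, SE 0.16), which also rests on the labels of pair 1. Simulated libraries, drawn without sex or heart differences, gave 42.7% of genes changed 2-fold and 0.51% of genes changed 1.5-fold.

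The authors' deposited tables for the 2 genotype comparisons also held no gene at an adjusted p under 0.05. Ctnnb1 had log2 fold changes of -0.22 in the LV and -0.43 in the RV in the authors' deposited tables. The smallest adjusted p in the authors' deposited table was 0.841 in the LV and 0.918 in the RV. At an unadjusted p under 0.05 the authors' deposited tables held 794 genes in the LV and 764 in the RV, where uniform p-values give 709 of 14179. By edgeR from the counts there were 442 and 418 genes. Their log2 fold changes had a Pearson correlation across genes of 0.93 in the LV and 0.922 in the RV with those computed here from the counts. For 4 entries of the authors' deposited table for the RV the values per library equal those of another gene of the count table, within 0.001 on the log2 scale. In the authors' deposited table for the RV, the entry labelled Gja1 holds the values of Gm16104 (log2 fold change -1.30, adjusted p = 0.918) and the entry labelled Gm16104 those of Gja1 (-0.02, adjusted p = 0.987). In that authors' deposited table the entry labelled Hey2, a transcription factor of ventricular heart muscle, holds the values of Gm6206 (-0.96, adjusted p = 0.918) and the entry labelled Gm6206 those of Hey2 (0.01, adjusted p = 0.996). From the counts, Hey2 had a log2 fold change of 0.02 (SE 0.24) in the RV.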

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

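The interaction and respiratory chain values come from lists fixed in advance. The values for pair 1 rest on the 326 genes of a fit chosen after the data were seen, and those for control LV 2 on 23 on-off genes picked from the data. The tests of explanations for pair 1 and for control LV 2 and the sarcomere comparison were chosen after the values were seen, and the length test before.

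For 5 lists the interaction term passed camera with the preset correlation, and for none with an estimated one (adjusted p = 0.808 with an estimated correlation for each list) or by fry. The median interaction was -0.21 for fatty acid oxidation, 0.34 for mitochondrially encoded genes, 0.23 for immediate early genes, 0.25 for interferon response and 0.33 for cell cycle genes. Without the pair labelled WntLOF 1 only the mitochondrially encoded list passed by camera, and fatty acid oxidation did not (adjusted p = 0.524). The direction of the camera test turned there for cell cycle genes (median 0.029, adjusted p = 0.96). The mitochondrially encoded call ended without certain single libraries, such as control LV 3 (median 0.18) or the library labelled WntLOF RV 2 (0.19). It held without others, such as control LV 1 (0.54). In 89 of 100 draws of the 12 libraries into 4 groups, at least 312 genes reached an unadjusted p under 0.05, the real count, and the highest other draw had 1972. Chance cannot be excluded for the gene count. The draws did not keep replicate numbers balanced over the groups, although left and right libraries of equal number were correlated.

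The ventricle genes of the pair labelled WntLOF 1 lie opposite to their labels. The right minus left ventricle score was -1.53 in this pair, 2.56 in pair 2 and 1.002 in pair 3. A mixture of both ventricles in both libraries is argued against by scores of 0.81 and -0.72, whose smaller size is 0.715; from the 67 genes called without the control pair numbered 2 they were 1.16 and -0.48. A reversal by Wnt loss in every heart is argued against by the other 2 pairs, the smaller of which is 1.002. An exchange of the ventricle labels within this pair may account for the value of -1.53. Mir6236 was lower in the library labelled RV in all 3 pairs. It was picked by a call that uses these labels, so it cannot decide about an exchange. In controls its mean ran the other way (9.94 CPM in the LV and 12.1 CPM in the RV). A change in the heart of this pair alone was not tested.

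The library labelled control LV 2 is closest to the library labelled WntLOF RV 1. Control LV 2 shares the state of 100% of 23 on-off genes with both libraries labelled WntLOF 1 and 87.0% with control RV 2, a difference of 3 genes (Nxpe4, Rpsa-ps10 and Gm13453), while the other left and right libraries of equal number share 95.7% to 100% and control RV 2 shares 87.0% with both libraries labelled WntLOF 1. Of these 3 genes, Rpsa-ps10 and Gm13453 are pseudogene or predicted models, whose counts are uncertain. At Hsd17b7 and Gm5514 both control LV 2 and control RV 2 had the state of every Wnt LOF library, opposite to the other controls. The cause was not tested. The chi-square per gene of control LV 2 and the library labelled WntLOF RV 1 was 3.11, the lowest of 66 pairs, with the next at 10.5. This is above the sampling noise of 1, which covers counting error only, and argues against 1 set of reads deposited under both names. A shared heart is a candidate explanation for the value of 100%, while a second library or run of the same tissue and close relatives with the same alleles stay open.

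By camera with the preset correlation, respiratory chain genes lay higher in the RV in control (median 0.23) and Wnt LOF hearts (0.26), but neither passed with an estimated correlation (adjusted p = 0.533 and 0.961 with an estimated correlation) or by fry. Without control LV 3 the control median was 0.15. Leaving out 1 library gave Wnt LOF medians from 0.14 to 0.41. Among 10000 random lists matched on expression and transcript length the list stood at the 99.4th percentile in Wnt LOF hearts and higher in control hearts, which argues against length as the whole cause. The matched lists themselves had medians of 0.09 and 0.16, so part of the shift is shared with genes of like length and expression. In control hearts a higher share of heart muscle cells as the whole cause is argued against by the sarcomere median of -0.030, whose bootstrap interval (-0.12 to 0.10) lies below that of the respiratory chain (0.19 to 0.29), while endothelial (-0.15) and matrix genes (-0.17) lay lower and neuronal and Schwann cell markers (0.41) higher. In Wnt LOF hearts such a share stays open, since the sarcomere median of 0.024, with 19 of 27 members above 0, has an interval (0.0058 to 0.18) that overlaps that of the respiratory chain (0.15 to 0.33), and a difference between the ventricles and chance stay open in both. The percentiles and intervals treat genes as independent and measure the spread over genes, not over libraries.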

How the results depend on the processing

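The alternatives that leave out doubted libraries, add a sex term, or combine the block with the compared groups alone were chosen after the data were seen. Over 18 fits each, both genotype comparisons called 0 genes. Ctnnb1 stayed between -0.34 and -0.07 in the LV and between -0.45 and -0.27 in the RV, never called. Over the alternatives 1544 values of named genes stayed uncalled and moved by less than the within-group SD of log2 CPM. Another 15 stayed uncalled but moved further. The test was passed by 5 values (Kcnd2 in 4 fits of the controls alone and Kcna5 in 1). The sex term called 0 genes by edgeR in every comparison. For control RV against LV, the compared groups alone called 9 genes, with the replicate block 326, without control LV 2 and no block 1, with the block but without the control pair numbered 2, 67, and leaving out the libraries labelled WntLOF LV 1 and WntLOF RV 1, with or without control LV 2, 2. For Wnt LOF RV against LV, the replicate block within genotype called 1 gene (Mir6236), the compared groups with the block 1, and leaving out the doubted libraries 2. The interaction called 1 with the block within genotype. The replicate block over all groups changed no count of genes. Leaving out 1 library at a time gave 0 to 1 genes for Wnt LOF RV against LV. The cause of these moves was not tested.

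Lists called fell to 0 in all 5 comparisons with an estimated correlation and with fry. Leaving out 1 library gave 0 to 8 lists in the LV comparison, 4 to 8 in the RV comparison, 8 to 13 in control RV against LV, 2 to 6 in Wnt LOF RV against LV and 2 to 9 in the interaction. Without the libraries labelled WntLOF LV 1 and WntLOF RV 1, 10 lists passed in Wnt LOF RV against LV and 1 in the interaction, and without control LV 2 too, 11 and 3. Of the values of lists called, 283 kept their call over the alternatives and 131 lost it with the same direction of the test. The median had the other sign in 5 of the 131: matrix genes in the RV 3 times without WntLOF RV 1, interferon genes in the interaction without control LV 2 (-0.023) and cardiac transcription factors in controls without control LV 3 (0.016). The test's direction turned for matrix genes in the RV without control RV 3 (median 0.020; range when 1 library was left out -0.0041 to 0.21), for cell cycle genes in the interaction without WntLOF LV 1 (0.039; range 0.039 to 0.47) and without the doubted pair (0.029), and for interferon genes in the interaction without all 3 doubted libraries (-0.15). The cause was not tested.

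The correlation of the Wnt LOF effect between ventricles ran from 0.108 to 0.308 when 1 library was left out, and was 0.406 without the doubted pair and 0.379 without all 3; the cause was not tested. Counts of 10 splits per comparison are too few for a share under 0.05. The real counts at an unadjusted p under 0.05 and the highest other splits were 442 and 1508 (LV), 418 and 1272 (RV), 757 and 1452 (control) and 746 and 2448 (Wnt LOF). At least as many genes as in the real split came from 8, 9, 4 and 6 of the 10 splits. The Wnt LOF split with 2448 genes called 120, where the real split called 0, which points to an untested structure of the libraries: it sets WntLOF LV 1, LV 2 and RV 1 against the other 3. The split of WntLOF LV 1, RV 2 and RV 3 against the others called 2 genes, with 1146 at an unadjusted p under 0.05. The controls with the block gave 326 in the real split and at most 10 in the others (1 of 10). Only 4 of these splits, too few as well, part all 3 pairs, and the 3 that are not real called 0. The correlation was 0.187 in the real split of hearts and at most 0.568 in others, with 8 of 10 as high.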

Other observations

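Sex-linked genes followed the replicate number and not the group. In replicate 3 of every group the Y-linked gene Ddx3y stood between 102 and 136 CPM, and in all other libraries it was under 1 CPM. Xist, the RNA that silences an X chromosome, stood between 494 and 580 CPM in replicates 1 and 2 and at 4.31, 7.05, 3.59 and 25.1 CPM in replicate 3 of control LV, control RV, WntLOF LV and WntLOF RV. The first principal component held 24.6% of the variance and set replicate 3 of each group apart from replicates 1 and 2.

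Ventricle effects were correlated across genes, which are not independent replicates, between genotypes (Pearson 0.261 with all libraries). Of the 326 genes called between control ventricles, 87.1% had the same sign in Wnt LOF hearts.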
